A study of Mus musculus with 2 samples.

How the data were processed

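The deposited matrices hold raw UMI counts per gene and barcode, as whole numbers, for 2 pooled libraries of 5 mice each, made per the labels with the 10x Genomics Single Cell 3' v3.1 kit and loaded with about 1600 cells for a target of 1000. Per the submitters' processing notes the authors used Cell Ranger 5.0 with STAR on mm10 (GRCm38) and Seurat 3.2.2, while the matrix header names Cell Ranger 5.0.1. The matrices have 32285 genes, of which 40 symbols repeat, and the barcodes had been filtered before, since the lowest held 500 UMIs. They list 21068 barcodes (noise only) and 24209 barcodes (AAV-Isl1 plus noise), 21.1 and 24.2 times the target. Both numbers also lie far above the about 1600 cells loaded. Either most barcodes are not separate whole cells or the labelled cell numbers do not hold. Barcodes with few UMIs could be droplets without a whole cell. Which of these holds was not tested, and kept barcodes are called cells below. The libraries share 145 barcodes (0.688% of the noise-only barcodes). Coordinates are from GENCODE vM21. Counts come from the 3' end of annotated transcripts, and the labels do not say whether RNA from the vector maps to the annotated Isl1 gene.

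Cells with at least 300 genes and at most 20% mitochondrial UMIs passed the filter (19953 and 22672). Doublets were called with Scrublet in scanpy, run per library with an expected rate of 0.06. Its automatic threshold called 1210 doublets in the noise-only library and 1 in the AAV-Isl1 library, so the noise-only threshold of 0.198 was used in both, a choice made after these calls were seen, which removed 1210 (6.06%) and 798 (3.52%). Of all barcodes, 89.0% and 90.4% were kept. Of the kept cells, 47.5% and 45.0% had under 1000 UMIs. Counts were normalized to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen in each library and combined (3130 genes), and cells of both libraries were clustered together without batch correction on 50 principal components with 15 neighbours and Leiden resolution 1.0.

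A cluster was named after the class with the most fixed markers at least 4-fold above the other cells and seen in at least 10% of its cells. At least 3 such markers were needed, 1 of them among the 10 genes with the highest fold, and no other class could have more markers among those 10. Of 37 clusters, 25 were named, giving 16 classes, and 12 were left unnamed. After the clusters were seen, the 32 marker classes were merged to 27 (organ of Corti supporting, sulcus, limbus and root cells into cochlear non-sensory epithelium, B with plasma cells, and neutrophils with their progenitors), and a cluster led by Otol1 or Vwf was kept out of cochlear non-sensory epithelium or Schwann or satellite glia. The first is called the Otol1 cluster. The second, cluster 28, held 67 and 50 cells and was left unnamed. Classes are called X-like because they rest on markers alone. Classes with at least 100 cells in each library (12) and unnamed clusters with at least 90 (10) were compared, the latter limit set after cluster sizes were seen.

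UMIs were summed per class and library and divided by all UMIs of the class (CPM). Ratios have exact conditional binomial intervals, CPM exact Poisson intervals and shares of cells exact Clopper-Pearson intervals, each at 95%. They treat UMIs or cells as independent and cover counting error only. A count of 0 allows up to 3 counts, and ratios against 0 use 3. No test was made between the groups, since each is 1 library. For 28 gene lists, the median log2 ratio of members with at least 20 UMIs was taken where at least 5 were measured, with the range of 500 Poisson redraws and the percentile among 10000 random lists of equal size matched in 20 bins of expression. These percentiles describe the libraries and are no test between conditions. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs and leaving out shallower cells; the 7 hair cell genes for this were picked after the clusters were seen.

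Named genes followed 1 rule. Isl1 came first, and other candidates had at least 50 UMIs in the class, at least 20 CPM in a library, an interval that excludes 1, and at least 10% of the highest CPM of any class in the library where they were higher, as a guard against free RNA. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin and T cell receptor genes and unnamed models were not candidates. The 12 highest and 12 lowest ratios were taken in hair cell-like and cochlear non-sensory epithelium-like cells (1 of the latter is not reported here), 6 and 6 in the 4 other classes with the most cells, and 10 and 10 over all kept cells, besides 2 to 4 list members with the most UMIs in a class. The values of Pou4f3, Slc26a5, Spp1, Cib3, Xirp2, Otol1 and Tectb in hair cell-like cells fall outside that rule and were picked after their values were seen. Genes picked for extreme ratios have ratios that counting error inflates. The markers, gene lists, named-gene rule and alternatives were fixed before the data were examined, apart from the choices named here as made later and 4 alternatives added afterwards: the automatic doublet thresholds, the removal of cells with the most Isl1 UMIs, hair cell-like cells without the sub-cluster with the most Otol1 UMIs, and fibrocyte or mesenchymal-like cells of the cluster led by Fxyd2 and Kcnk2 alone.

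Alternatives covered the cell filter (at least 500 genes and at most 10% mitochondrial UMIs, or none), doublet removal, clustering resolutions of 0.5 and 2.0, leaving 288 genes over 2-fold apart between the libraries out of clustering, scaling each gene within its library, another random seed, TMM (edgeR), median of ratios and a total without mitochondrial, hemoglobin and ribosomal protein genes as scaling, thinned cells, and list members from 1 or 100 UMIs. The other resolutions, the left-out genes, the scaling of genes within a library and the other seed were applied to class shares only. Isl1 ratios, list medians and named genes were not computed again under those clusterings. The scalings of totals moved the log2 ratio of all genes by over 0.1 only for the Otol1 cluster (-0.10, median of ratios) and erythroid-like cells (0.20, reduced total).

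The steps were tested on Poisson counts simulated for each gene from class totals, in which 200 genes were changed. UMIs clumped in single cells and genes that vary together were not simulated, so the rates below hold for counting error only. Intervals held the true ratio for 95.8% of unchanged genes at the depth of Schwann or satellite glia-like cells and for 96.3% at that of hair cell-like cells, and median folds of 1.98 and 2.00 were found for genes made 2-fold different. For the 67 measured genes made 2-fold different, intervals held the true ratio in 88.1% and 95.5%. For the 66 and 65 made 4-fold different they held it in 93.9% and 96.9%. At the depth of Schwann or satellite glia-like cells the shares for 2-fold and 4-fold lay below the nominal 95%. For the 67 genes made 1.5-fold different, intervals held the true ratio in 100% at both depths. Random lists lay outside the central 95% of matched lists in 4.25% and 3.50% of draws, and lists made 1.5-fold higher lay above it in 100% and 99% of draws. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.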

Results

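Single-cell RNA sequencing counted UMIs (unique molecular identifiers, 1 per captured mRNA molecule) in dissociated inner ear tissue, labelled sensory epithelium, of CBA/CaJ mice aged 4 to 6 weeks. The labels describe 2 groups with 5 mice each, pooled into 1 library per group. Ears of the AAV-Isl1 plus noise group had received an adeno-associated virus carrying Isl1, a gene for a LIM homeodomain transcription factor that acts in the development of the inner ear and its neurons. Untreated opposite ears of the same animals made up the noise-only group. Noise of 105 dB between 1 and 20 kHz lasted 2 h, and tissue was taken 2 days later. The noise-only library held 38330528 UMIs in 21068 barcodes, and the AAV-Isl1 library held 40268563 UMIs in 24209 barcodes. After filtering, 18743 noise-only cells with a median of 1048 UMIs and 21874 AAV-Isl1 cells with a median of 1086 UMIs were kept. These kept barcodes are called cells, but each library holds more of them than the about 1600 cells loaded per the labels. With 1 pooled library per group, no difference could be tested against the variation between mice, and every interval given is a 95% interval for counting error only. No paired analysis was possible because the ears of each group were pooled into 1 library. Folds and log2 ratios are AAV-Isl1 plus noise over noise only.

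The first comparison asked whether Isl1 RNA was higher in the treated library and in which cells. Isl1 (ENSMUSG00000042258; GRCm38 chromosome 13, 116298281 to 116309689, minus strand) was far higher in hair cell-like cells of the AAV-Isl1 library, at 524 CPM (UMIs per 1000000 UMIs of the class) against 36.6, a 14.3-fold ratio (7.45 to 31.6; 330 and 9 UMIs). In the Otol1 cluster, which shared markers with cochlear epithelium but was led by Tectb and Otol1, genes for proteins of the acellular membranes over sensory cells, Isl1 stood at 1222 against 156 CPM, 7.82-fold (5.01 to 12.9). Cluster 15, an unnamed cluster led by Vmo1, had 76.4 against 10.7 CPM, 7.13-fold (3.80 to 14.8). Cluster 8, an unnamed cluster led by Igfbp6, had 60.5 against 15.5 CPM, 3.90-fold (1.99 to 8.50, from 67 and 10 UMIs). The ratio was 10.3 without the 5 cells with the most Isl1 UMIs in each library. Those cells held 13 of the 67 UMIs but 7 of the 10 noise-only UMIs. Cochlear non-sensory epithelium-like cells had 175 against 109 CPM, 1.59-fold (1.24 to 2.04). Neuron-like cells held 2358 of the 2677 Isl1 UMIs of the noise-only library and 2559 of the 4103 of the AAV-Isl1 library, and their Isl1 level was slightly lower, 257 against 304 CPM (0.845-fold, 0.799 to 0.894). Over all kept cells the ratio was 1.41 (1.35 to 1.49). Erythroid-like cells, which should not express Isl1, had 18.9 CPM (12.3 to 28.0) and 7.07 CPM (1.46 to 20.7). Schwann or satellite glia-like cells were close to that background at 23.5 against 5.55 CPM, 4.23-fold. The ratio was 8.48 with at least 500 genes and at most 10% mitochondrial UMIs per cell. It was 2.73 without the 5 cells with the most Isl1 UMIs, which held 32 of the 68 UMIs of the AAV-Isl1 library. Other populations near that background also had higher ratios. Macrophage-like cells had 19.9 against 2.52 CPM (7.88-fold, 2.47 to 40.1), with 29 of their 33 UMIs in 1 cell. The unnamed clusters 22 and 5 had ratios of 6.26 and 5.84 and endothelial-like cells 3.91, while stria intermediate cell-like cells had 0.981.

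Most Isl1 UMIs of hair cell-like cells of the AAV-Isl1 library lay in few cells, while those of the Otol1 cluster were spread over more. In the AAV-Isl1 library, 11 of 406 hair cell-like cells (2.71%, 1.36 to 4.80) held at least 5 Isl1 UMIs. So did 35 of 357 cells of the Otol1 cluster (9.80%, 6.92 to 13.4). In the noise-only library these were 0 of 112 and 0 of 90, with exact upper bounds of 3.24% and 4.02%. The intervals of the shares thus overlapped in hair cell-like cells. A single hair cell-like cell held 94 of the 330 Isl1 UMIs and the top 5 cells together 200. In the Otol1 cluster 129 of 357 cells (36.1%, 31.1 to 41.4) had an Isl1 UMI, and the top 5 cells held 155 of 596. A sub-cluster of 53 and 19 hair cell-like cells, with 107 of the 113 and 23 of the 26 Otol1 UMIs of the class in the AAV-Isl1 and noise-only libraries, held 124 and 1 Isl1 UMIs. Without that sub-cluster the Isl1 ratio of hair cell-like cells was 9.67 (4.82 to 22.7). With every cell thinned to 1000 UMIs, Isl1 was seen in 42 of 303 hair cell-like cells (13.9%, 10.2 to 18.3) of the AAV-Isl1 library and in 3 of 106 (2.83%, 0.588 to 8.05) of the noise-only library. The same measure gave 33.9% (27.0 to 41.3) and 13.2% (4.41 to 28.1) in the Otol1 cluster, 5.40% and 1.39% in cluster 15, 12.6% and 9.54% in cochlear non-sensory epithelium-like cells, and 23.1% and 25.0% in neuron-like cells. In cochlear non-sensory epithelium-like cells the intervals of the shares overlapped with thinning (8.88 to 17.2 and 7.29 to 12.2) and without it, where the shares were 13.9% (11.1 to 17.1) and 14.1% (11.9 to 16.5) at median depths of 1002 and 1288 UMIs. Erythroid-like cells gave 1.58% and 0.621%. Before thinning, Isl1 was seen in 14.5% and 8.04% of hair cell-like cells, at median depths of 1207.5 and 1809 UMIs, and in 2.38% and 1.67% of erythroid-like cells, at 1929 and 2290 UMIs.

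**Figure D1:**
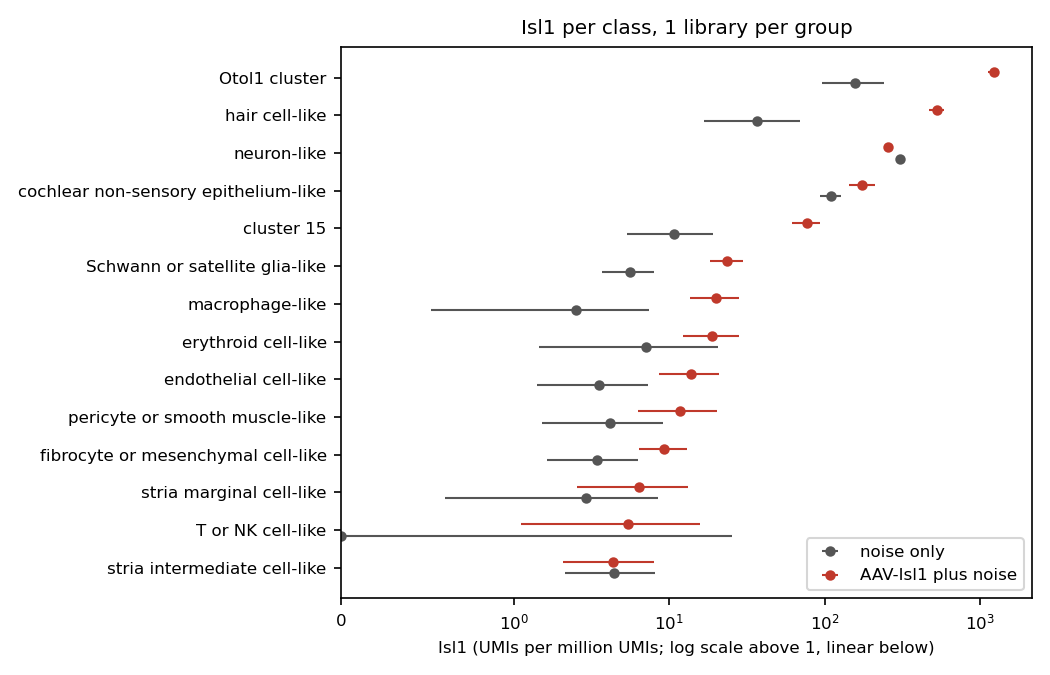
Isl1 level (CPM, log scale above 1 and linear below) in each class of the noise-only (grey) and AAV-Isl1 plus noise (red) libraries, with 95% Poisson intervals. The Otol1 cluster (156 and 1222) and hair cell-like cells (36.6 and 524) have the widest gaps in level, while neuron-like cells stand at 304 and 257.

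The second comparison asked which cell classes were captured in each library. Hair cell-like cells were a larger part of the AAV-Isl1 library, 406 cells (1.86%, 1.68 to 2.04) against 112 (0.598%, 0.492 to 0.719), a 3.11-fold ratio (2.51 to 3.86). The markers used did not separate cochlear from vestibular hair cells: Slc26a5, the gene for the outer hair cell motor prestin, had 7 and 10 UMIs in the class, 6 and 10 of them in a sub-cluster of 8 and 7 cells. Spp1, known from vestibular hair cells, had 25669 against 30718 CPM in the class, and Cib3 and Xirp2, among its 10 leading genes, had 1218 against 1339 and 802 against 953 CPM. No vestibular marker set was compared, and hair cell-like cells and the Otol1 cluster were assigned neither to the cochlea nor to the vestibular organs. Neutrophil-like cells, granulocytes of blood and marrow, differed most among the named classes, with 490 cells (2.24%) against 25 (0.133%), 16.8-fold (11.2 to 26.2). Dendritic cell-like cells, with 37 against 5 cells, had a 6.34-fold ratio (2.49 to 20.7). B or plasma cell-like (4.37-fold, 3.36 to 5.77), T or NK cell-like (3.80-fold, 3.11 to 4.66), erythroid-like (3.20-fold, 2.71 to 3.80) and macrophage-like cells (1.61-fold, 1.45 to 1.79) also took larger shares. Neuron-like cells made up 6.73% against 4.14% (1.63-fold, 1.49 to 1.78). Schwann or satellite glia-like cells, which wrap nerve fibres and neuron bodies, took a smaller share, 17.6% against 33.6% (0.524-fold, 0.503 to 0.546), as did cochlear non-sensory epithelium-like cells with 539 cells (2.46%) against 907 (4.84%), 0.509-fold (0.457 to 0.567). The Otol1 cluster took 1.63% against 0.480% (3.40-fold, 2.69 to 4.33).

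Other named classes lay closer together. Fibrocyte or mesenchymal-like cells had a ratio of 1.47 (1.37 to 1.58), stria intermediate cell-like cells 1.22 (1.13 to 1.32), stria marginal cell-like cells 1.16 (1.02 to 1.32), pericyte or smooth muscle-like cells 0.784 (0.721 to 0.852) and endothelial-like cells 0.947 (0.875 to 1.03). Ciliated or middle ear epithelium-like cells had 1.20 (0.823 to 1.76) from 70 against 50 cells. Unnamed clusters held 24.4% and 26.6% of the cells. Shares describe dissociated and captured cells, not the tissue, and 1 class with a larger share lowers the shares of the others. With at least 500 genes and at most 10% mitochondrial UMIs the ratio of B or plasma cell-like cells was 8.45, with each gene scaled within its library that of the Otol1 cluster was 1.35, and at a clustering resolution of 0.5 that of fibrocyte or mesenchymal-like cells was 0.935.

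**Figure D2:**
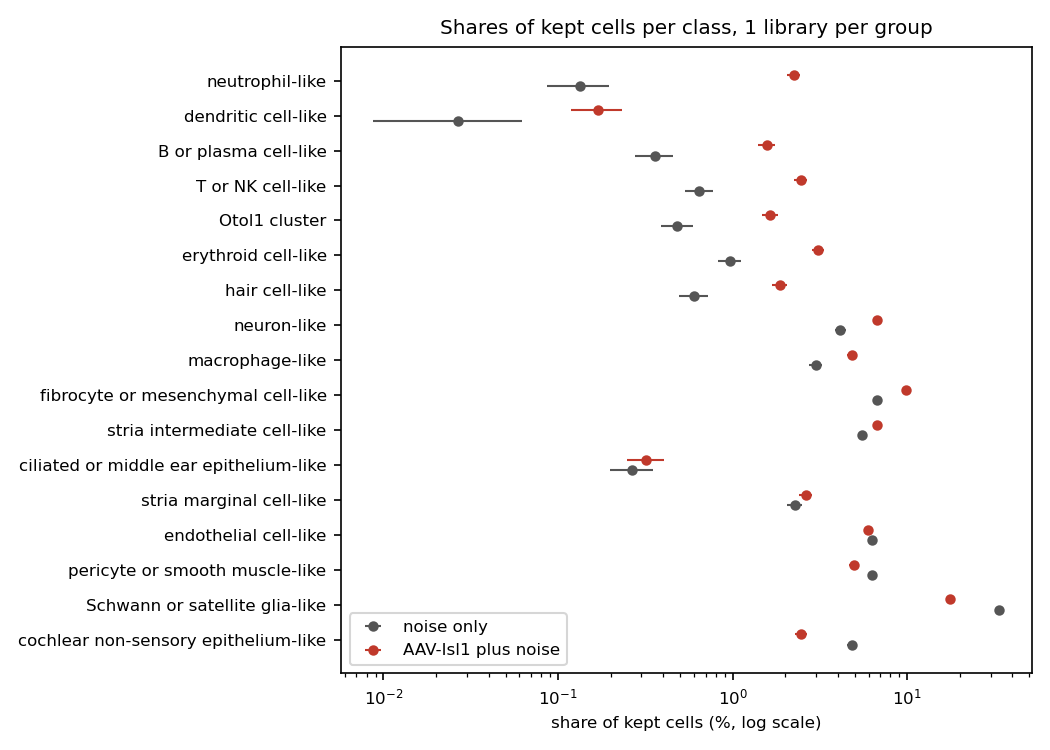
Share of kept cells (%, log scale) in each named class and the Otol1 cluster of the noise-only (grey) and AAV-Isl1 plus noise (red) libraries, with exact 95% binomial intervals, ordered by ratio. Neutrophil-like cells (0.133% and 2.24%) have the highest ratio and cochlear non-sensory epithelium-like cells (4.84% and 2.46%) the lowest.

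In hair cell-like cells, most measured genes of a hair cell list were lower in the AAV-Isl1 library. The median log2 ratio of hair cell transcription and bundle genes was -0.28 (-0.48 to -0.14), with 3 of 22 measured members above 1 and 19 below, at percentile 0.04 of 10000 random lists matched on expression. Otof, a calcium sensor for synaptic vesicle release, had 569 against 826 CPM (0.688-fold, 0.578 to 0.821), Espn, an actin-bundling protein of stereocilia, 1897 against 2186 CPM (0.868-fold, 0.783 to 0.962), and Myo6, an unconventional myosin of hair cells, 816 against 827 CPM (0.988-fold, 0.838 to 1.17). Ocm, the calcium buffer oncomodulin, had 556 against 1173 CPM (0.474-fold, 0.405 to 0.556), but 180 of its 350 and 240 of its 288 UMIs came from a sub-cluster of 8 and 7 cells. Pou4f3, a transcription factor for hair cell survival, had 210 against 358 CPM (0.585-fold, 0.444 to 0.776); it and Slc26a5 were picked from the list after their values were seen. Genes of the Otol1 cluster had higher ratios in the class, Otol1 with 180 against 106 CPM (1.70-fold, 1.10 to 2.71) and Tectb with 71.5 against 36.6 CPM (1.95-fold, 0.942 to 4.54). Without the sub-cluster with the most Otol1 UMIs, the median of the hair cell list was -0.30 (-0.46 to -0.14) with 17 of 22 members below 1, and the ratios of Pou4f3 and Otof were 0.537 (0.397 to 0.728) and 0.646 (0.534 to 0.785).

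Among 7 hair cell genes whose detection was compared, the shares of Pou4f3 lay apart by more than their intervals with and without thinning, those of Myo7a only without it, and those of the others in neither case. After thinning to 1000 UMIs, Pou4f3 was seen in 64 of 303 cells (21.1%, 16.7 to 26.2) against 44 of 106 (41.5%, 32.0 to 51.5), Otof in 39.9% (34.4 to 45.7) against 50.0% (40.1 to 59.9), and Tmc1, a subunit of the mechanotransduction channel, in 33.0% against 32.1%. Slc17a8, the vesicular glutamate transporter, was seen in 14.5% against 18.9%, Myo7a, a stereocilia myosin, in 10.9% against 12.3%, Ocm in 9.57% against 7.55%, and Slc26a5 in 0.990% against 1.89%. Without thinning the shares were 27.3% and 51.8% for Pou4f3, 48.5% and 62.5% for Otof, 41.6% and 49.1% for Tmc1, 20.0% and 25.0% for Slc17a8, 14.5% and 29.5% for Myo7a, 9.85% and 11.6% for Ocm, and 0.985% and 2.68% for Slc26a5. Of 568 thinned erythroid-like cells of the AAV-Isl1 library, 0 had a UMI of Pou4f3, Myo7a, Ocm or Slc26a5, which allows up to 0.528%, and Otof, Tmc1 and Slc17a8 were each seen in 0.176%. Each of the 7 genes was seen in 0 of 161 thinned erythroid-like cells of the noise-only library, which allows up to 1.86%. Median depths before thinning were 1207.5 and 1809 UMIs in hair cell-like and 1929 and 2290 UMIs in erythroid-like cells.

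Besides Isl1, the named genes with the highest ratios in hair cell-like cells included the interferon-inducible genes Ifi27l2a, at 866 against 89.6 CPM (9.67-fold, 6.32 to 15.6), and Ifi27, at 338 against 110 CPM (3.08-fold, 2.06 to 4.78). S100b, a calcium-binding protein of glia and supporting cells, had a 2.65-fold ratio (1.95 to 3.67), and 3.76-fold (2.44 to 6.04) without the sub-cluster with the most Otol1 UMIs. Otos, the gene for otospiralin of fibrocytes, had a 6.88-fold ratio, with 348 of its 441 UMIs in 1 cell, and its log2 ratio was 1.11 with each cell thinned to 1000 UMIs against 2.78 without. Vps4b, Bc1, Odr4, Zfp445, Nudt9, Trappc3 and Ap1m2 had ratios from 2.39 to 3.51. Among genes with the lowest ratios was Lgals1, the lectin galectin-1 (0.289-fold, 0.187 to 0.443, with 35 of its 54 noise-only UMIs in 1 cell). Pcp4, a calmodulin regulator (0.429-fold, 0.374 to 0.492), and Calb2, the calcium buffer calretinin (0.439-fold, 0.346 to 0.556), were also among them. Of their noise-only UMIs, 91 of 401 and 36 of 137 lay in 1 cell. Their log2 ratios were -0.69 and -0.83 with at least 500 genes and at most 10% mitochondrial UMIs per cell. With each cell thinned to 1000 UMIs they were -0.68 and -0.81, against -1.22 and -1.19 as reported. Magi3, Tmx4, Smim18, Odf3b, Tunar, Txndc9, Inpp5f, Galk1 and Ap1s1 had ratios from 0.350 to 0.465.

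Several fixed gene lists were higher in hair cell-like cells. Interferon response genes had a median log2 ratio of 0.88 (0.49 to 1.38) with 11 of 13 members above 1, among them Ifitm3, a restriction factor against virus entry (2.13-fold, 1.5 to 3.09), and Bst2, the tether of budding virus (1.79-fold, 1.10 to 3.07). MHC class I and antigen processing genes stood at 0.83 (0.50 to 1.72) with 7 of 7 above 1, led in UMIs by B2m, the light chain of MHC class I (2.17-fold, 1.39 to 3.55). H2-K1, a class I heavy chain, had 66 and 4 UMIs (6.44-fold, 2.40 to 24.3). Gap junction and potassium recycling genes had 0.42 (0.23 to 0.86) with 9 of 11 above 1, including Slc12a2, a sodium, potassium and chloride cotransporter (1.89-fold, 1.21 to 3.06). The interferon median was 0.48 with no doublets removed and 0.23 with list members from 1 UMI counted, and that of MHC class I genes was 0.35 in the latter case. Without the sub-cluster with the most Otol1 UMIs, the interferon median was 0.56 (0.12 to 1.07), with 6 measured members, all above 1. MHC class I genes then had 1.02 (0.67 to 1.91) from 6 members, and gap junction and potassium recycling genes 0.59 (0.39 to 1.32) from 9.

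Wnt pathway genes had 0.41 (0.02 to 0.72) in hair cell-like cells, with 5 of 6 above 1, such as Ctnnb1, the gene for beta-catenin (1.59-fold, 1.06 to 2.43), and Dkk3 (1.54-fold, 1.06 to 2.30), but the median was -0.14 with members from 1 UMI counted. Lists of cell death and protection were not distinguishable from 0 at this depth. The p53 and apoptosis genes had -0.33 (-0.67 to 0.17), anti-apoptotic and pro-survival genes -0.03 (-0.26 to 0.35), antioxidant and glutathione genes -0.08 (-0.19 to 0.15), heat shock and chaperone genes -0.03 (-0.15 to 0.15), and LIM homeodomain factors and partners -0.01 (-0.34 to 0.45). With each cell thinned to 1000 UMIs the medians of p53 and apoptosis genes and of anti-apoptotic and pro-survival genes were on the other side of 0, at 0.32 and 0.37.

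In cochlear non-sensory epithelium-like cells, interferon and MHC class I genes were higher and supporting cell genes lower in the AAV-Isl1 library. The median log2 ratio was 0.44 (0.33 to 0.58) for interferon response genes, with 22 of 24 members above 1, such as Ifitm3 (1.79-fold, 1.61 to 2.00) and Bst2 (1.37-fold, 1.26 to 1.5). It was 0.48 (0.35 to 0.80) for MHC class I and antigen processing genes, with 13 of 14 above 1, such as H2-D1 (1.84-fold, 1.59 to 2.12) and B2m (2.02-fold, 1.72 to 2.36). Supporting cell identity genes had -0.22 (-0.37 to -0.08), at percentile 0.23, with 11 of 15 below 1. Hes1, a Notch pathway repressor of transcription, had 198 against 338 CPM (0.584-fold, 0.477 to 0.710), and S100a1, a calcium-binding protein, 0.887-fold (0.865 to 0.909). The 47 cytosolic ribosomal protein genes were all below 1, with a median of -0.14 (-0.17 to -0.13), and epithelial cytoskeleton and junction genes had -0.16 (-0.21 to -0.02).

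Extracellular matrix and collagen genes of this class had 0.37 (0.10 to 0.65), where Dcn, the proteoglycan decorin, was higher (2.44-fold, 1.90 to 3.12) and Lum, the proteoglycan lumican, lower (0.520-fold, 0.424 to 0.634). MHC class II genes had 2.83 (2.11 to 3.37) with 6 of 6 above 1, and Cd74, the class II invariant chain of antigen-presenting cells, had 75 and 30 UMIs (5.74-fold, 3.71 to 9.08). Complement genes had 0.91 (0.12 to 1.76), where C1qa, made by macrophages, had a 2.58-fold ratio (1.43 to 4.67) and Clu, the chaperone clusterin, 0.768-fold (0.723 to 0.814). Wnt pathway genes had 0.45 (-0.02 to 0.59), and -0.10 with each cell thinned to 1000 UMIs. Nuclear-encoded oxidative phosphorylation genes had 0.07 (0.01 to 0.12) and -0.0018 under TMM scaling, while the median of MHC class II genes was 1.48 with members from 1 UMI counted.

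Among the named genes with the highest ratios in cochlear non-sensory epithelium-like cells was Mme, the membrane peptidase neprilysin, at 70.4 against 22.7 CPM (3.104-fold, 1.95 to 4.99). Sema3b, a secreted semaphorin (2.59-fold, 1.71 to 3.94), Ube2l6, an enzyme that attaches the interferon-induced modifier ISG15 (2.29-fold, 1.39 to 3.78), and Ly6e, an interferon-inducible surface protein (2.26-fold, 1.55 to 3.28), were also among them. Fbxo8, Epb41l2, Mettl16, Zeb2, Kmt5a, Fmnl2 and Gjc3 had ratios from 2.17 to 2.29. Sec22a had 7 and 59 UMIs (0.272-fold, 0.105 to 0.597), Apoc3, an apolipoprotein, 24 and 182 (0.303-fold, 0.189 to 0.465), and Col9a2, a chain of collagen IX, 9 and 60 (0.344-fold, 0.150 to 0.698). Bex1, Nsun2, Mta3, Cr1l, Rab17, Fbxl12, Psph, Trim26 and Ginm1 had ratios from 0.349 to 0.446. With each cell thinned to 1000 UMIs the log2 ratios of Sec22a and Fbxl12 were -3.74 and -3.40, against -1.88 and -1.23 without.

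Interferon response genes were higher in the AAV-Isl1 library in some classes and not in others. Their median log2 ratio was 1.84 (1.45 to 2.01) in cluster 15, with 25 of 26 members above 1, 1.67 (1.44 to 2.07) in the Otol1 cluster, with 13 of 14, and 1.63 (1.45 to 1.87) in cluster 23, an unnamed cluster with fibrocyte markers, with 30 of 30. Ifit1, an antiviral RNA-binding protein, had 443 against 65.2 CPM (6.80-fold, 5.26 to 8.90) in cluster 15 and 1065 against 245 CPM (4.35-fold, 3.64 to 5.21) in cluster 23. Ifi27 was 3.47-fold (2.44 to 5.11) and Ifitm3 3.95-fold (2.51 to 6.56) in the Otol1 cluster. Macrophage-like cells had a median of 0.26 (0.10 to 0.35) and neuron-like cells 0.25 (0.12 to 0.40). Endothelial-like cells had -0.13 (-0.20 to -0.04), with 23 of 32 members below 1, such as Irf1, an interferon-induced transcription factor (0.795-fold, 0.714 to 0.885). Schwann or satellite glia-like cells had -0.09 (-0.20 to 0.05), and fibrocyte or mesenchymal-like cells -0.01 (-0.12 to 0.10). With no doublets removed, the median of cluster 15 was 1.25, and with members from 1 UMI counted that of the Otol1 cluster was 0.88.

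**Figure D3:**
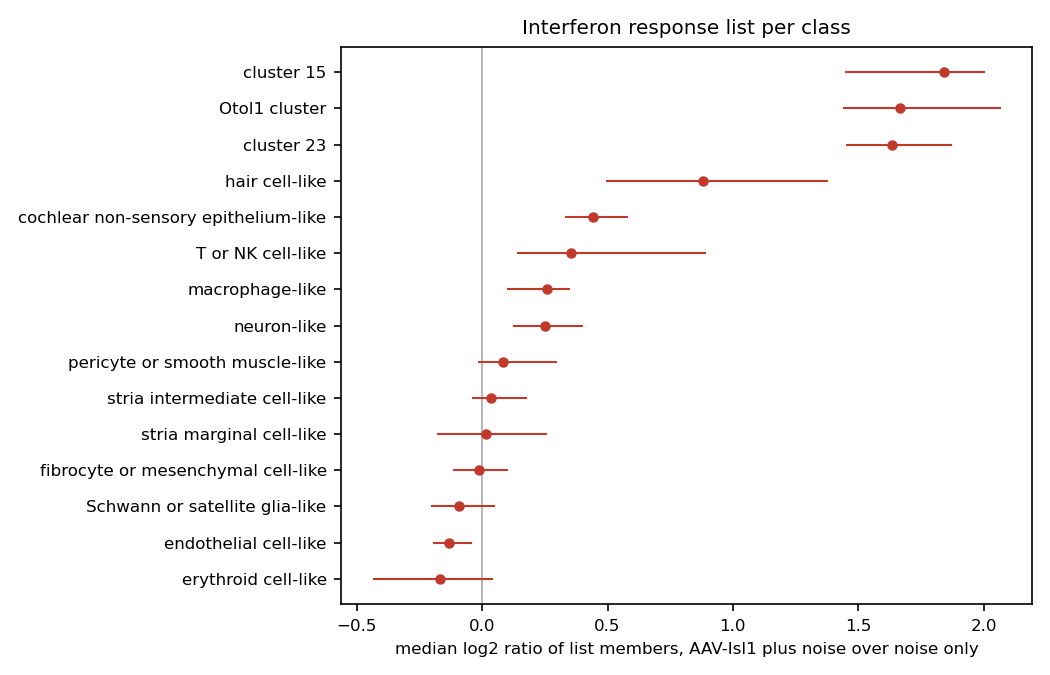
Median log2 ratio (AAV-Isl1 plus noise over noise only) of interferon response genes in each class, with the 95% range of 500 Poisson redraws of the counts. Cluster 15 (1.84), the Otol1 cluster (1.67), cluster 23 (1.63) and hair cell-like cells (0.88) have the highest medians of the populations plotted, and endothelial-like cells stand at -0.13.

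MHC class I and antigen processing genes were higher in most classes compared. Their median log2 ratio was 1.22 (1.01 to 1.37) in cluster 23, 1.17 (0.86 to 1.31) in cluster 15, 0.86 (0.60 to 1.10) in neuron-like, 0.78 (0.39 to 1.39) in Otol1 cluster, 0.66 (0.49 to 0.78) in macrophage-like and 0.58 (0.46 to 0.75) in Schwann or satellite glia-like cells. Pericyte or smooth muscle-like cells had 0.49 (0.27 to 0.67) and fibrocyte or mesenchymal-like cells 0.24 (0.12 to 0.53), while endothelial-like cells had -0.14 (-0.20 to -0.04). In Schwann or satellite glia-like cells the class I heavy chains H2-D1 (3.25-fold, 2.98 to 3.54) and H2-K1 (2.99-fold, 2.59 to 3.44) and the immunoproteasome subunit Psmb9 (2.52-fold, 1.81 to 3.53) were among the named genes with the highest ratios, and the log2 ratio of Psmb9 was 2.54 with each cell thinned to 1000 UMIs against 1.33 without. B2m was 2.24-fold (1.91 to 2.64) in neuron-like cells. Whether RNA of immune cells in the same droplets adds to the MHC class I values was not tested in any class. Neutrophil and MHC class II genes were also higher in Schwann or satellite glia-like and neuron-like cells.

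Immediate early genes, which respond to stimulation and tissue handling within minutes, went in opposite directions between classes. Their median log2 ratio was -0.25 (-0.30 to -0.20) in Schwann or satellite glia-like, -0.27 (-0.30 to -0.21) in macrophage-like, -0.22 (-0.27 to -0.19) in pericyte or smooth muscle-like and -0.46 (-0.59 to -0.35) in erythroid-like cells. It was 0.32 (0.22 to 0.36) in neuron-like cells, 0.42 (0.32 to 0.57) in stria marginal cell-like cells and 0.47 (0.43 to 0.55) in cluster 15. Fos, part of the AP-1 transcription factor, had 0.770-fold (0.755 to 0.784) in Schwann or satellite glia-like, 1.26-fold (1.20 to 1.32) in neuron-like and 1.38-fold (1.25 to 1.53) in stria marginal cell-like cells. Jun, its partner, had 0.858-fold (0.829 to 0.888), 1.02-fold (0.970 to 1.08) and 1.57-fold (1.35 to 1.82) in the same classes.

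Genes of neutrophils and antigen-presenting cells were also higher in classes of other lineages, beside the larger shares of neutrophil-like and macrophage-like cells. Neutrophil granule and secretory genes had a median log2 ratio of 3.098 (2.59 to 3.53) in Schwann or satellite glia-like, 3.01 (2.72 to 3.45) in neuron-like, 1.87 (1.09 to 2.80) in fibrocyte or mesenchymal-like and 0.50 (0.17 to 0.81) in endothelial-like cells. With members from 1 UMI counted it was 1.39, 2.44 and 0.18 in the first 3 of these classes, and with no doublets removed it was 4.04 in neuron-like and 1.13 in endothelial-like cells. S100a9, an abundant calcium-binding protein of neutrophils, stood at 131 against 14.3 CPM in Schwann or satellite glia-like and at 46.9 against 0.903 CPM in neuron-like cells. MHC class II genes had 2.77 (2.22 to 3.62) in Schwann or satellite glia-like and 3.32 (2.73 to 4.08) in neuron-like cells, where the median was 1.64 with members from 1 UMI counted and 4.22 with no doublets removed. In macrophage-like cells, which are antigen-presenting cells, the median was 1.36 (1.31 to 1.83), and H2-Aa, a class II chain, had 2127 against 607 CPM (3.50-fold, 3.23 to 3.80).

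In endothelial-like cells Icam1, an adhesion molecule for leukocytes (0.419-fold, 0.341 to 0.514), Ptgs2, the inducible prostaglandin synthase COX-2 (0.417-fold, 0.307 to 0.561), and the amino acid transporter Slc38a5 (0.351-fold, 0.265 to 0.460) were lower in the AAV-Isl1 library, as were Col6a6, Hfe and Fbln5 (0.317-fold to 0.397-fold). Cxcl9, an interferon-gamma-induced chemokine, had 48 and 2 UMIs (29.9-fold, 7.84 to 254), and Fabp4, a fatty acid binding protein, 172 and 29 (7.39-fold, 4.96 to 11.4). Ccl21a, a chemokine of lymphatic endothelium, had 131 UMIs in 5 cells against 1 UMI. Prkca, Aqp1 and Slc36a2 had ratios from 3.56 to 4.67, but with no doublets removed the log2 ratios of Prkca and Slc36a2 were 0.75 and 0.52, against 2.22 and 1.83 with doublets removed. The log2 ratio of Ccl21a was 3.03 with each cell thinned to 1000 UMIs against 7.35 without, and that of Fabp4 was 3.76 with at least 500 genes and at most 10% mitochondrial UMIs per cell against 2.88.

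In Schwann or satellite glia-like cells Usp18, a brake on interferon signalling (0.380-fold, 0.254 to 0.554), Cdr1os (0.424-fold, 0.349 to 0.511) and Col3a1, a fibrillar collagen (0.568-fold, 0.426 to 0.748), were lower, and Ciao3, Zfp503 and Myg1 had ratios from 0.537 to 0.577. Chst2 (2.56-fold, 2.03 to 3.23) and Ppp2cb (3.33-fold, 2.17 to 5.21) were higher, but the log2 ratio of Ppp2cb was 0.59 with each cell thinned to 1000 UMIs against 1.74 without. Prl, the pituitary hormone prolactin, had 243 and 17 UMIs, of which 224 lay in 1 cell, and its log2 ratio was -1.60 with at least 500 genes and at most 10% mitochondrial UMIs per cell, where that of Ciao3 was -0.25 against -0.90.

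In fibrocyte or mesenchymal-like cells Spink8 (3.19-fold, 2.63 to 3.90), Ucma, a matrix protein of cartilage (2.87-fold, 2.58 to 3.20), H2-K1 (2.26-fold, 2.05 to 2.49) and Cebpb, a transcription factor of inflammation (2.07-fold, 1.76 to 2.45), were higher, as were Rbp4 and Igfbp3 (2.05-fold to 2.13-fold). Kcnk2, a potassium channel (0.526-fold, 0.468 to 0.591), and Fxyd2 (0.529-fold, 0.481 to 0.581), were lower, and Cables1, C1ql1, Daam2 and Kctd12 had ratios from 0.412 to 0.543. Fxyd2 and Kcnk2 led 1 of the clusters of the class, which held 332 of its 2160 cells in the AAV-Isl1 library and 294 of 1259 in the noise-only library. Within that cluster the ratios were nearer 1, 0.801 (0.711 to 0.902) for Kcnk2 and 0.803 (0.730 to 0.883) for Fxyd2. The log2 ratio of Ucma there was -0.095. Ucma is a leading gene of another cluster of the class, where no ratio was taken, so this value does not bear on its higher level. In pericyte or smooth muscle-like cells Spink8 (4.18-fold, 2.85 to 6.25) and Cdh1, the epithelial cadherin (4.13-fold, 2.43 to 7.33), were higher, and Kcnk1, Gas2l3, Lgi4 and Pllp had ratios from 3.41 to 4.07. With no doublets removed the log2 ratios of these 6 genes were lower, 0.91 for Spink8, 0.92 for Cdh1 and from 0.60 to 1.02 for the others, against 1.77 to 2.06 with doublets removed. Spink8 and Pllp were also leading genes of clusters named Schwann or satellite glia-like, while the other genes were not. Cdr1os (0.227-fold, 0.134 to 0.368), Ccl19, a chemokine for T cells (0.345-fold, 0.241 to 0.485), and Arntl, a core clock factor (0.369-fold, 0.170 to 0.734), were lower, as were Rgs6, Fam53a and Wfdc1 (0.366-fold to 0.393-fold).

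Over all kept cells, where each ratio also reflects the share of the class that makes the gene, Plac8, a gene of blood cells (5.48-fold, 4.66 to 6.48), Pcp4 (2.72-fold, 2.63 to 2.81), Cks2, a cell division cofactor (2.44-fold, 2.15 to 2.78), Ucma (2.37-fold, 2.18 to 2.57) and Psmb9 (1.76-fold, 1.62 to 1.91) were higher. Clec2l, Shisa8, Otos, Fam107b and Kcnb2 had ratios from 1.80 to 1.98, but the log2 ratio of Kcnb2 was 0.24 with each cell thinned to 1000 UMIs against 0.85 without. Des, the muscle filament desmin (0.476-fold, 0.430 to 0.527), the homeobox genes Irx5 (0.495-fold, 0.459 to 0.533) and Irx3 (0.547-fold, 0.517 to 0.578), Nkd1, a Wnt inhibitor (0.501-fold, 0.454 to 0.552), and Hes1 (0.622-fold, 0.595 to 0.649) were lower, and Rgs16, Cdh6, Itga8, Adgra2 and Tnfrsf19 had ratios from 0.544 to 0.617.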

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

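The automatic doublet thresholds, the removal of cells with the most Isl1 UMIs or of a sub-cluster of hair cell-like cells, and the values within 1 cluster of fibrocyte or mesenchymal-like cells were chosen after the data were seen, and the other alternatives were not. Under the alternatives, 110 class share ratios, 31 Isl1 ratios and 670 named gene ratios stayed within the counting interval of the reported value, as did 302 medians of gene lists that stood apart from random lists and 400 other list medians. Outside it were 14, 3, 58, 46 and 41, besides 1, 0, 2, 3 and 1 that reversed a direction whose interval excluded no difference. The alternatives for resolution, left-out genes, scaling within a library and seed entered the class share ratios alone. How Isl1 ratios, gene ratios and list medians depend on those clusterings was not examined. Unless given, the cause was not tested. The number of kept cells (18743 and 21874 as reported) was 11154 and 12889 with at least 500 genes and at most 10% mitochondrial UMIs, 19858 and 23411 with no filter, 19953 and 22672 with no doublets removed, and 22671 in the AAV-Isl1 library with the automatic thresholds, by the construction of each setting.

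Share of kept cells per class, as a fold: with at least 500 genes and at most 10% mitochondrial UMIs, B or plasma cell-like was 8.45, Schwann or satellite glia-like 0.460, T or NK cell-like 2.59, endothelial-like 0.826 and pericyte or smooth muscle-like 0.685. At resolution 0.5, Schwann or satellite glia-like was 0.546 and fibrocyte or mesenchymal-like reversed to 0.935, and at resolution 2.0 Schwann or satellite glia-like was 0.496 and macrophage-like 1.10. With each gene scaled within its library, Schwann or satellite glia-like was 0.567, erythroid-like 2.56 and the Otol1 cluster 1.35. With genes over 2-fold apart left out of clustering, neuron-like was 1.92. With the automatic doublet thresholds, Schwann or satellite glia-like was 0.499 and neuron-like 1.79. No cluster was named B or plasma cell or erythroid cell with those genes left out, nor was there an Otol1 cluster at resolution 0.5, so these settings gave no value.

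Isl1 UMIs per library, as a fold with at least 500 genes and at most 10% mitochondrial UMIs, were 1.33 over all kept cells and 8.48 in Schwann or satellite glia-like cells. Removing the cell or the 5 cells with the most Isl1 UMIs from each library gave ratios of 11.5 and 12.5 in hair cell-like cells. The same removals gave 8.56 and 10.3 in the Otol1 cluster, and removing 5 cells gave 10.3 in cluster 8. In the noise-only library those 5 cells held 5 of 9, 10 of 20 and 7 of 10 Isl1 UMIs of these populations. Removal thus lowered both levels, so these ratios cannot show whether the difference rested on few cells. The named gene ratio of Prl in Schwann or satellite glia-like cells reversed to a log2 of -1.60 with at least 500 genes and at most 10% mitochondrial UMIs. That of Ucma in fibrocyte or mesenchymal-like cells reversed to -0.095 within the cluster led by Fxyd2 and Kcnk2, of which Ucma is not a leading gene.

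Gene list medians per class (log2) with each cell thinned to 1000 UMIs: immediate early genes -0.15 in Schwann or satellite glia-like, 0.12 in endothelial-like, -0.62 in erythroid-like, 0.13 in fibrocyte or mesenchymal-like, -0.40 in macrophage-like, 0.17 in neuron-like, -0.37 in pericyte or smooth muscle-like cells and 0.56 in cluster 15; interferon response -0.28 in Schwann or satellite glia-like, 0.69 in cochlear non-sensory epithelium-like, -0.20 in endothelial-like cells and 2.15 in the Otol1 cluster; MHC class I 0.18 in erythroid-like, 0.73 in pericyte or smooth muscle-like, 0.27 in stria intermediate cell-like cells and 0.81 in cluster 15. In cochlear non-sensory epithelium-like cells thinning gave -0.10 for Wnt pathway, 0.12 for oxidative phosphorylation, 0.011 for mitochondrially encoded and -0.18 for ribosomal protein genes.

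With TMM and median of ratios scaling, cochlear non-sensory epithelium-like cells had -0.0018 and -0.010 for oxidative phosphorylation (reversed from 0.07), 0.060 and 0.051 for mitochondrially encoded, -0.21 and -0.22 for ribosomal protein, and -0.23 and -0.24 for cytoskeleton and junction genes, and cluster 15 had 0.43 for immediate early genes with TMM. With the total without mitochondrial, hemoglobin and ribosomal protein genes, immediate early genes of erythroid-like cells had -0.66. With at least 500 genes and at most 10% mitochondrial UMIs, immediate early genes had -0.34 in Schwann or satellite glia-like and -0.68 in erythroid-like cells, and interferon response 1.41 in the Otol1 cluster. With no doublets removed, immediate early genes had -0.30 in Schwann or satellite glia-like, 0.089 in endothelial-like, 0.20 in neuron-like and -0.19 in pericyte or smooth muscle-like cells, and interferon response had 0.48 in hair cell-like cells and 1.25 in cluster 15.

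With list members from 1 UMI, MHC class I had 0.87 in Schwann or satellite glia-like and 0.35 in hair cell-like cells, MHC class II 1.48 and extracellular matrix 0.71 in cochlear non-sensory epithelium-like cells, and interferon response 0.23 in hair cell-like cells and 0.88 in the Otol1 cluster. Wnt pathway reversed to -0.14 in hair cell-like cells and neutrophil granule genes to -0.23 in cluster 15. With members from 100 UMIs, MHC class I had 0.77 in Schwann or satellite glia-like and 0.49 in neuron-like cells, and interferon response 1.25 in cluster 23.

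Share of cells with an Isl1 UMI (%) in the AAV-Isl1 library, thinned to 500 UMIs: 22.97 in the Otol1 cluster, 2.39 in cluster 15, 7.98 in cochlear non-sensory epithelium-like, 7.14 in hair cell-like and 13.2 in neuron-like cells, and in the noise-only library 4.52 in cochlear non-sensory epithelium-like and 15.5 in neuron-like cells. Without thinning it was 10.3 in cluster 15, 72.8 in neuron-like cells and 13.9 in cochlear non-sensory epithelium-like cells, and in the noise-only library 14.1 in cochlear non-sensory epithelium-like and 86.9 in neuron-like cells. More UMIs per cell raise such shares by construction.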

Other observations

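Besides the classes above, unnamed clusters differed in size. Cluster 22, led by the transporter genes Slc6a13 and Slc22a2, made up 5.29% of the AAV-Isl1 library and 1.99% of the noise-only library (2.66-fold, 2.36 to 2.99). Cluster 14, with markers of tympanic border cells, made up 2.28% and 5.58% (0.408-fold, 0.366 to 0.455). Neuron-like cells fell into a cluster of 1242 and 724 cells led by Calb2 and a cluster of 231 and 52 cells led by Pcp4. Within hair cell-like cells, the sub-cluster of 53 and 19 cells with the most Otol1 UMIs (107 and 23) held 124 and 1 Isl1 UMIs, another of 37 and 13 cells held 116 and 3, and the sub-cluster of 8 and 7 cells with the prestin UMIs held 52 and 2.

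Of the tests that follow, those of immune cell RNA in the interferon pattern and of cells with Isl1 UMIs carrying it were written before their results were seen, and the others were chosen after the results were seen.

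The first pattern was the higher Isl1 level of hair cell-like cells and the Otol1 cluster. Free Isl1 RNA at 1 level in all droplets of the AAV-Isl1 library was excluded as the whole source, since the smallest difference that the intervals allow, 399.6 CPM, lay above the upper bound of 28.0 CPM in erythroid-like cells. Another mix of the sub-clusters found was excluded as the whole source, within counting error. Isl1 UMIs were 2.79 times the upper bound predicted from the sub-cluster mix in hair cell-like cells (329 against 118). In the Otol1 cluster they were 3.25 times that bound (596 against 183). A rare subtype with high Isl1 inside a sub-cluster was not excluded in hair cell-like cells. There, 11 of 406 cells (2.71%) held at least 5 Isl1 UMIs, and 0 of 112 noise-only cells allow up to 3.24%. Transcription from the vector may account for the 46 hair cell-like and Otol1 cluster cells with at least 5 Isl1 UMIs in the AAV-Isl1 library. In the noise-only library 0 cells of these populations held as many. Vector transcription cannot be told apart from transcription of the endogenous gene, since 3' end counts give no vector sequence. Neuron-like cells also held at least 5 Isl1 UMIs, in 183 of 776 noise-only cells (23.6%) and 100 of 1473 AAV-Isl1 cells (6.79%). Their median depths were 10285.5 and 6616 UMIs.

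The second pattern was the higher interferon response of clusters 15 and 23, the Otol1 cluster and hair cell-like cells. Free RNA at 1 level in all droplets was excluded as the whole source. The list's summed CPM was higher by at least 426.5 in each of these populations. The largest difference allowed in Schwann or satellite glia-like or endothelial-like cells was -226. Those reference classes were picked after their low list medians were seen. A lower level of their own could hide added free RNA, so a part from free RNA was not excluded. RNA of macrophages or T cells in the same droplets was excluded, since their markers were higher by at most 0.0279 of what such RNA would need. Pooled over the 4 populations, cells with an Isl1 UMI held 1.11 times (1.02 to 1.20) the list UMIs of cells without one, which met the bound set beforehand for cells with Isl1 carrying the pattern. The ratio was 1.20 (1.07 to 1.35) in cluster 15, 1.09 (0.918 to 1.29) in the Otol1 cluster, 1.07 (0.812 to 1.39) in hair cell-like cells and 0.884 (0.697 to 1.11) in cluster 23, so that its interval excluded 1 only in cluster 15. Cells without an Isl1 UMI also held 2.25, 1.92, 2.68 and 1.86 times the list UMIs of noise-only cells in cluster 15, cluster 23, the Otol1 cluster and hair cell-like cells, so that explanation was left open. A response to the virus, to its delivery or to Isl1 may underlie the pattern, and these cannot be told apart in this design because 1 group received all of them (ratio 1.11).

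The third pattern was the larger share of blood and marrow cell classes in the AAV-Isl1 library. A smaller share of Schwann cells would lift all other classes alike. It was excluded as the whole source, since the lower bound of the neutrophil-like fold was 11.2 and the upper bound of the endothelial-like fold 1.03. A part from it was not excluded, which matters most for smaller ratios such as that of macrophage-like cells (1.61-fold). Marrow carried over in the dissection is a candidate explanation for the erythroid-like class. There, dividing precursors made up 18.1% (15.3 to 21.3) of the class against 0.556% (0.0141 to 3.06). Marrow was not tested for neutrophil-like cells, the named class that differed most. Their markers past the naming rule included Cebpe, Fcnb, Chil3, Camp, Ngp and Ltf from the neutrophil progenitor list. Mpo, Elane, Prtn3, Ctsg and Ms4a3 of that list were not among them. Camp and Ngp led the cluster, and they and Ltf are also on the neutrophil list. For T or NK cell-like cells (3.80-fold), no value separated marrow from tissue cells, and an immune response to the treatment stays untested.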
